A study of Rattus norvegicus with 6 samples.

How the data were processed

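RNA from cultured neonatal rat ventricular cardiomyocytes was measured on 6 one-colour arrays that carried probes for long non-coding RNAs (lncRNAs) and for mRNAs. Per the labels, 3 samples were untreated controls and 3 had been exposed to 10 µM isoproterenol, an agonist of beta-adrenergic receptors, for 24 h. Per the labels' protocols the cells came from newborn Sprague-Dawley rats, fibroblasts had been depleted by letting them attach first, and the cultures were kept in serum-free medium before treatment. The labels also speak of passaged cells and the series text of transfection, which does not match primary cells given isoproterenol, and this stays unresolved. The series text calls the replicates biological, but the labels do not tie a replicate to a litter or a culture day, so the p-values measure the spread between these samples and no more.

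Per the file headers, the scans were read with Agilent Feature Extraction 11.0.1.1, and the deposited scanner files hold linear intensity values of the Cy3 channel, background-subtracted by that software, for 43040 spots per array. No array had a saturated spot. The authors also deposited a table of values for lncRNAs and one for mRNAs. A comparison with the scanner files showed that most of these deposited values lie close to quantile-normalized log2 intensities, with one highest value, 18.2, in every column of the mRNA table. The 95th percentile of the absolute difference was at most 0.00257 on slide 1, but 0.666 and 0.642 for isoproterenol replicates 2 and 3, and the cause was not tested. The tool that made them is not given in the sources used here.

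The scanner files name probes by design numbers only, whereas the deposited tables give transcript identifiers. The rows of the tables were therefore matched to probes by their values over the 6 arrays, after the scanner values had been mapped to the scale of the tables. A match was accepted when the Euclidean distance over the arrays was under 0.05 on the log2 scale and under 0.25 of the distance to the next best probe. Of 29788 distinct rows 29712 were matched, 9021 of lncRNAs and 20691 of mRNAs; 29375 were matched by values and 337 by a name alone. Of the probes that carried a name in both sources, 148 were also matched by values, all of them to the right row. The other 337 did not pass the match by values and were placed by name. All 29223 neighbouring pairs of rows matched by values followed the order of the probe numbers. A further 23 rows of the lncRNA table held no values, and 8609 probes absent from the tables took no part in the comparison. RefSeq accessions were named through a table of assembly GRCr8, which is not the build in the file headers. That table served for names and, through its gene positions, for which genes neighbour each other, and no coordinates are given. It named 13925 of 14724 NM accessions, 129 of 140 NR accessions and 408 of 6662 XR accessions. None of the 5967 Ensembl transcript identifiers among the mRNA probes could be named from it.

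For the comparison, log2 of the processed signal was taken for each array and its 75th percentile over non-control probes was subtracted. Control spots and spots with an outlier mark were left out and spots of one probe were averaged. A probe was tested when its signal was well above background on at least 3 of the 6 arrays, whatever their group. Each mRNA gene was represented by its brightest probe over all arrays, which gave 19975 genes, and each of 8952 lncRNA probes was an item of its own. Of 437 genes with more than one probe, 60 changed, and in 14 of these the probes differed in direction. Isoproterenol was compared with control by limma's moderated test in R, two-sided, with Benjamini-Hochberg adjustment within each kind of RNA and a threshold of 0.05. Items past the threshold are said to have changed, risen or fallen whatever the cause. Changes are log2 fold changes, isoproterenol minus control, with the SE of the model and n = 3 per group. A fold is given as "at least" where no array of one group was well above background; it sets the measured group mean against the mean over the other group's arrays of the lowest signal that was well above background, or of the probe's own signal if that was higher.

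Gene lists were tested with camera in limma at a preset correlation between genes of 0.01, with adjustment over 25 lists; each list was also tested with a correlation estimated from the data. The lists were fetal and hypertrophic cardiac genes, adult sarcomere genes, calcium handling and ion channels, adrenergic receptors and cAMP machinery, cAMP and immediate early targets, fatty acid oxidation, oxidative phosphorylation, glycolysis and glucose uptake, extracellular matrix and remodelling, cell cycle, p53 and apoptosis, endoplasmic reticulum stress, inflammatory cytokines and NF-kB targets, interferon response, oxidative stress response, ribosomal proteins, heat shock proteins and circadian clock. Lists of markers covered fibroblasts, smooth muscle and pericytes, endothelium, macrophages and leukocytes, epicardium and mesothelium, Schwann cells and neurons, and erythroid cells. A count "adjusted over the list alone" used the p-values of its members only.

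The lists, the tests, the alternatives and the rule for named genes were set before the data were examined. The rule took the 10 largest rises and the 10 largest falls among changed mRNA genes, up to 4 changed members of each list by size of change, the 5 largest rises and falls of lncRNA probes, and measured genes given whether changed or not, among them Nppa, Nppb, Myh7, Myh6, Acta1, Atp2a2, Rcan1, Adrb1, Pde4d, Nr4a1 and Crem. A further gene of that rule, Pde4b, is not analysed here, and some results under the rule are not reported here.

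The file headers place the 3 control arrays and isoproterenol replicate 1 on slide 1 and isoproterenol replicates 2 and 3 on slide 2. A fit with slide as a block takes the isoproterenol effect from slide 1 alone, where isoproterenol has 1 array. Its value, called the value within slide 1, is given beside the results. Its adjusted p takes the spread from the controls and the slide 2 arrays. Isoproterenol replicate 1 adds none, so that p does not measure the variation of treated samples on slide 1. Other alternatives were normexp background correction, applied to the median spot signal because the files used here hold no mean signal, quantile normalization, scaling to the median, scaling over probes detected on all arrays, the deposited values, other filters and probe rules, other variance models, the replicate number as a block and each array left out. A fit to slide 1 alone and quantile normalization combined with the slide block were added after the data had been seen.

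The procedure was tested on simulated arrays built from the real means. Of 50 changed genes per size among 19975, it recovered 0% at a log2 change of 0.5, 4% at 1, 88% at 2 and 96% at 3, and it called 3 of 19740 unchanged genes. A list of 35 genes lowered by 1 was the only list past the threshold. Simulated values were drawn independently for each gene and array, with no slide difference and no correlation between genes. The simulation therefore does not measure false calls arising from either. The number of arrays limits the precision. Tools were R 4.3.3 with limma 3.58.1, and Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.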

Results

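Neonatal rat ventricular cardiomyocytes left untreated or exposed to 10 µM isoproterenol for 24 h were compared, 3 arrays per group, to see which mRNAs and lncRNAs differ after beta-adrenergic stimulation. Isoproterenol is a synthetic catecholamine that is widely used to model the hypertrophic response of cardiomyocytes. On the 4 arrays of slide 1, which were control replicates 1 to 3 and isoproterenol replicate 1, between 97.5% and 99.7% of mRNA probes and between 94.0% and 99.1% of lncRNA probes were well above background. On the arrays of slide 2, isoproterenol replicates 2 and 3, the shares were 61.2% and 70.7% for mRNA and 41.2% and 51.4% for lncRNA. Median negative-control signals were 27, 28, 28 and 30 scanner units on slide 1 and 87 and 84 on slide 2. The 75th percentile of the signal was 514, 546, 519 and 562 on slide 1 and 198 and 240 on slide 2.

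**Figure D1:**
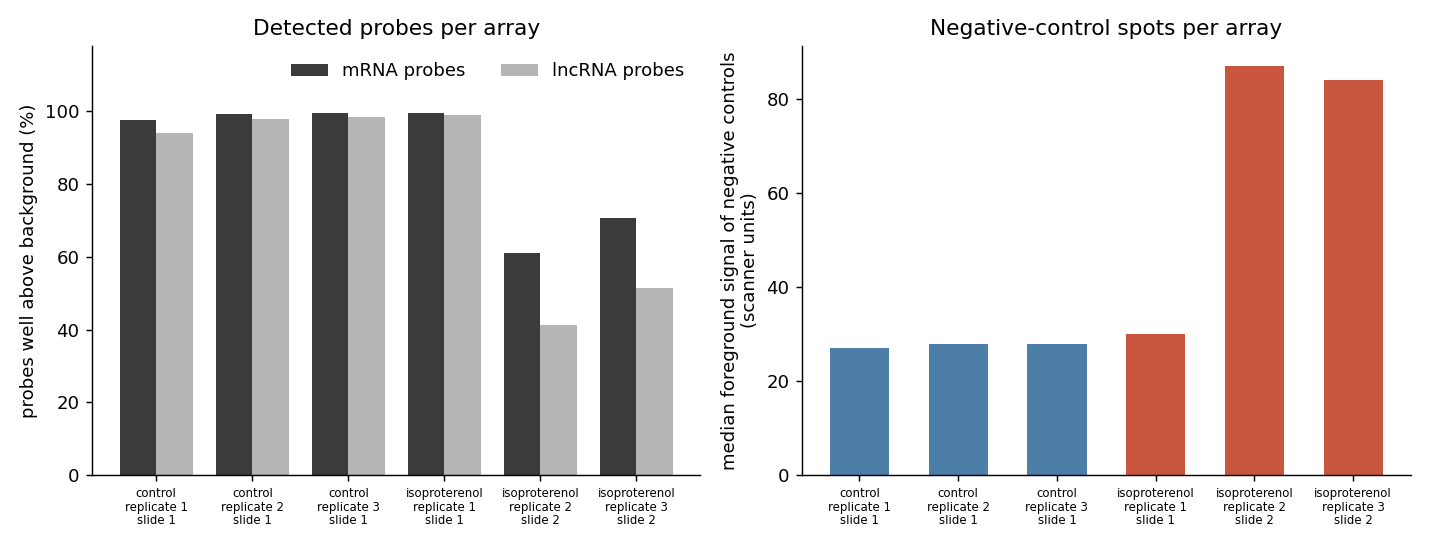
Left, percent of mRNA probes (dark bars) and lncRNA probes (light bars) well above background on each array; right, median foreground signal of negative-control spots in scanner units (blue: control; red: isoproterenol). The arrays of slide 2 detected 61.2% and 70.7% of mRNA probes and had negative-control signals of 87 and 84.

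Between isoproterenol and control 2769 of 19975 mRNA genes differed, of which 1721 were higher and 1048 lower with isoproterenol. Slide and treatment partly coincide in this comparison, and 931 of the genes were called again with slide as a block. Prl7a3, a member of the prolactin family, was at least 18.4-fold higher and was detected on 0 control arrays and 3 isoproterenol arrays (adjusted p = 0.00216). That bound holds for the processing used, since the log2 change of Prl7a3 ranged from 2.07 to 6.30 under the alternatives. Mfsd2a, a lipid transporter of the plasma membrane, rose by 4.84 ± 0.26 on the log2 scale and was detected on 2 control arrays. Vgf, a secreted neuropeptide precursor, rose by 4.66 ± 0.32, F2rl1, a protease-activated receptor, by 4.48 ± 0.41, and the chemokine Cxcl2 by 4.19 ± 0.37. Among the largest falls were those of Myom2, an M-band protein of the sarcomere, at −5.34 ± 0.21, and Adhfe1, at −5.07 ± 0.47 and detected on 1 isoproterenol array.

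Among the other leading rises, Clca4l was higher by 3.95 ± 0.24 (3.55 within slide 1), C9h6orf141 by 3.75 ± 0.26 (3.32) and Slc7a3, a cationic amino acid transporter, by 3.72 ± 0.43 (2.94). Among the other leading falls, Atp6ap1l was lower at −4.88 ± 0.40 (−5.02 within slide 1), Smim5 at −4.63 ± 0.28 (−4.21), Rxrg, a retinoid X receptor, at −4.51 ± 0.37 (−3.89), Lrrc39, a myosin-interacting protein of the M-band, at −4.49 ± 0.23 (−4.14), Pdk4 at −4.32 ± 0.28 (−4.08) and Slc25a34 at −4.24 ± 0.20 (−4.08). Smim5, Rxrg and Pdk4 were detected on 1 isoproterenol array and Atp6ap1l and Slc25a34 on 2. Under normexp Adhfe1, Smim5, Rxrg and Pdk4 fell by less, at −2.63, −2.38, −1.996 and −1.70. Rises also depended on processing: the lowest value under the alternatives was 2.41 for Mfsd2a, but 3.90 for Vgf and 3.61 for F2rl1. The within-slide values of Mfsd2a, Vgf, F2rl1 and Cxcl2 were 4.48, 4.09, 3.61 and 3.53, and those of Myom2 and Adhfe1 were −5.50 and −4.01. Every gene named in these leading groups passed the threshold with slide as a block, with adjusted p from 0.0166 to 0.0347. A transcript without a gene name was among the 10 leading genes in each direction and is not described here. In brackets after a gene's change stands its value within slide 1 and, where the gene did not pass there, the adjusted p of that value.

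A change of at least 2-fold was found for 2018 genes, 1259 higher and 759 lower. In all 2769 changed genes the 3 values of one group lay beyond the 3 of the other, as they did in 41.4% of the genes tested. Of the 1048 genes that fell, 285 were not detected on either slide 2 array. With slide as a block 1105 genes changed, 532 higher and 573 lower. Leaving out control replicate 1, 2 or 3 gave 1134, 175 or 140 genes, leaving out isoproterenol replicate 2 or 3 gave 853 or 506, and leaving out isoproterenol replicate 1, which places the groups on different slides, gave 10006. The split into higher and lower depended on scaling: normexp background correction gave 1860 and 669, and scaling over probes detected on all arrays 1173 and 1695. The median change of all genes was 0.07 in the comparison as given, 0.37 and −0.17 under these alternatives, and 0.13 under median scaling.

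**Figure D2:**
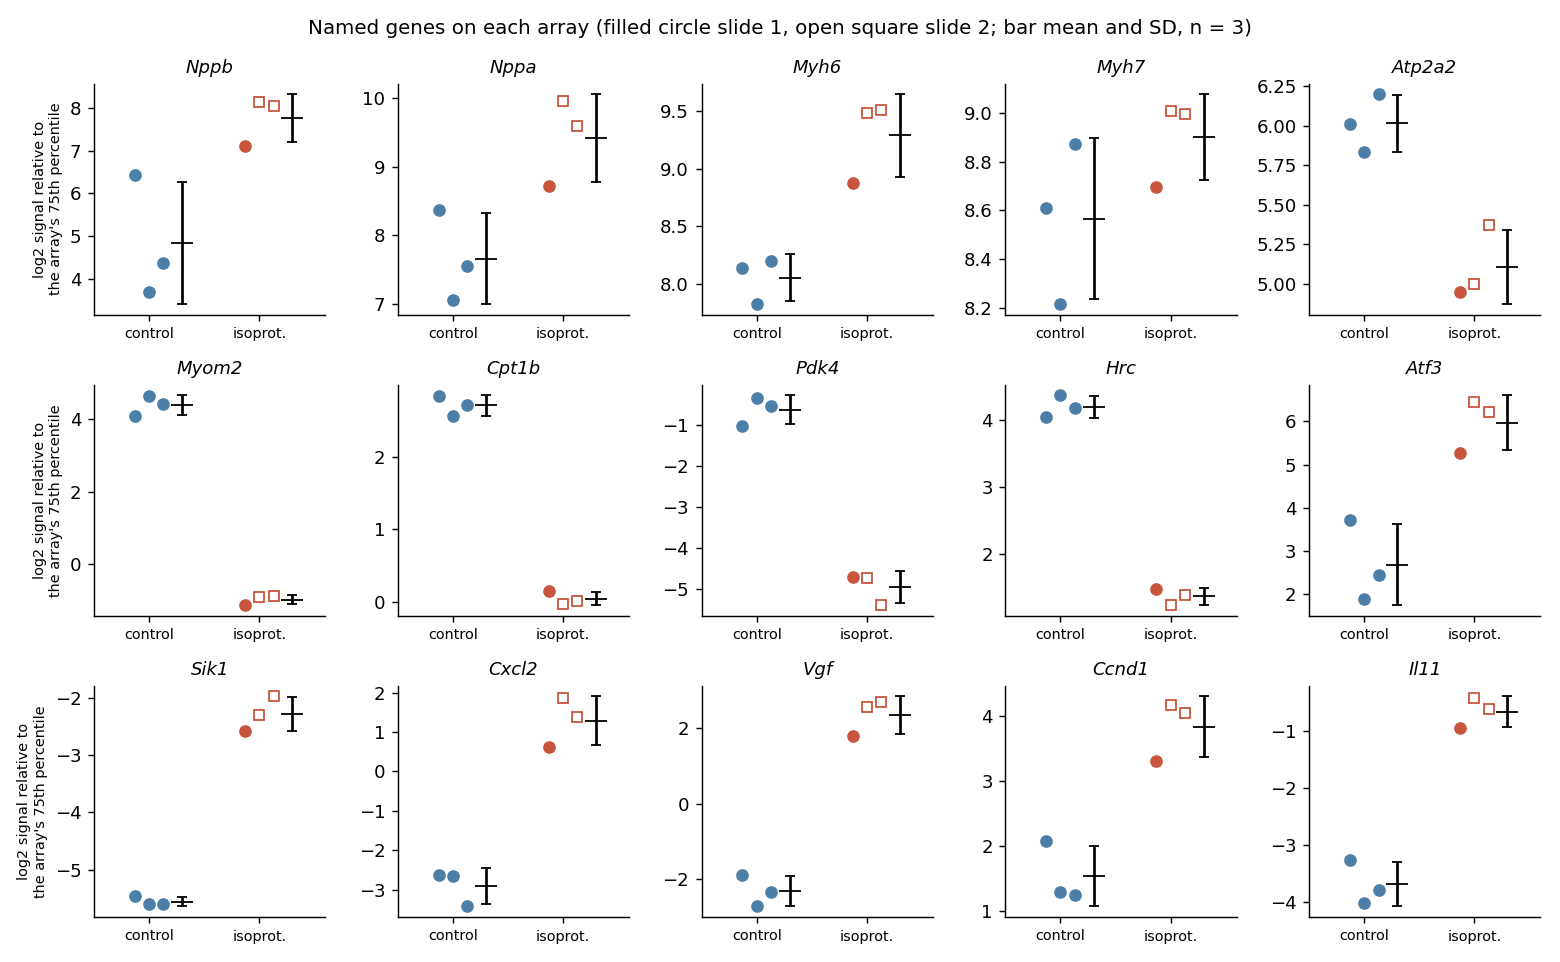
Log2 signal relative to the array's 75th percentile for 15 genes, one point per array (blue: control; red: isoproterenol; filled circles slide 1, open squares slide 2), with mean and SD, n = 3; axes do not start at 0. Atp2a2, Myom2, Cpt1b, Pdk4 and Hrc were lower with isoproterenol and the other genes shown were higher, though Myh7 did not pass the threshold.

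Natriuretic peptides and other genes of the fetal and hypertrophic programme moved in both directions. Nppb, which encodes brain natriuretic peptide, rose by 2.92 ± 0.70 (adjusted p = 0.0393) and Nppa, which encodes atrial natriuretic peptide, by 1.76 ± 0.44 (adjusted p = 0.0439), and Xirp2, a protein of the intercalated disc, rose by 3.35 ± 0.55. Nppc, which encodes C-type natriuretic peptide, fell, at −1.98 ± 0.28 (detected on 1 isoproterenol array; −0.13 under normexp, adjusted p = 0.731), and Ckm, muscle creatine kinase, at −1.96 ± 0.17. Acta1, skeletal alpha-actin, at 1.35 ± 0.50 (adjusted p = 0.113), Rcan1, a calcineurin target, at 1.93 ± 0.55 (0.061), and Myh7, beta myosin heavy chain, at 0.34 ± 0.23 (0.324), did not pass; Myh7 was at −0.24 under quantile normalization. Of 21 genes tested in the list 5 rose, 2 fell and 14 did not pass, and 8 rose and 2 fell when adjusted over the list alone. The list's median was 0.77 and camera gave adjusted p = 0.134, and adjusted p = 0.648 with an estimated correlation. Within slide 1 the median was 0.13 (adjusted p = 0.941). Within slide 1 Nppb was at 2.28 (adjusted p = 0.246), Nppa at 1.05 (0.272), Xirp2 at 2.57 (0.0997), Nppc at −1.62 (0.0599) and Ckm at −1.83 (0.0209), so of these genes Ckm alone passed there. Under quantile normalization Nppb and Nppa had adjusted p = 0.0782 and 0.0773. In control replicate 1 Nppa, Nppb, Acta1 and Rcan1 were highest among the controls. Without that array they were at 2.11, 3.72, 1.91 and 2.53, and the list passed the camera threshold (adjusted p = 0.0104). The list also passed with scaling over probes detected on all arrays (adjusted p = 0.0477).

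Sarcomere genes of the adult heart also went both ways. Myom2 fell, Trim63, a muscle ubiquitin ligase, fell, at −1.43 ± 0.22 (−1.61 within slide 1), Pdlim5, a Z-disc protein, rose by 1.59 ± 0.25 (1.36, adjusted p = 0.0676 there), and Myh6, alpha myosin heavy chain, rose by 1.23 ± 0.24 (adjusted p = 0.0225, 0.82 within slide 1, adjusted p = 0.0827, adjusted p = 0.0761 under quantile normalization). Of 20 genes tested 2 rose, 2 fell and 16 did not pass, with the same numbers when adjusted over the list alone. The median was 0.31, the mean −0.02 and camera's adjusted p 0.721, with adjusted p = 0.956 with an estimated correlation. Within slide 1 the median was 0.07 (adjusted p = 0.238), and under quantile normalization it was −0.24.

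Genes of calcium handling and ion channels were lower. Hrc, a calcium-binding protein of the sarcoplasmic reticulum, fell, at −2.83 ± 0.18 (−2.72 within slide 1), the potassium channel gene Kcnh2 at −2.27 ± 0.25 (−2.10) and Kcnip2, a subunit of the transient outward channel detected on 1 isoproterenol array, at −2.13 ± 0.32 (−2.56, adjusted p = 0.066 under quantile normalization, and −0.34 under normexp, adjusted p = 0.475). Kcne1, a subunit of the slow delayed rectifier, rose by 2.90 ± 0.31 (2.67). Atp2a2, the calcium pump of the sarcoplasmic reticulum, fell, at −0.91 ± 0.20 (adjusted p = 0.0331, −1.07 within slide 1, adjusted p = 0.0657, and not past the threshold under median scaling). Of 29 genes tested 1 rose, 8 fell and 20 did not pass, and 2 rose and 12 fell when adjusted over the list alone. Camera called the list lower (median −0.57, adjusted p = 6.35e-04, adjusted p = 0.211 with an estimated correlation), and within slide 1 the median was −0.52 (adjusted p = 2.10e-04), whereas under normexp the median was 0.12 with a camera call of lower (adjusted p = 4.56e-04).

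Of the adrenergic receptors and the cAMP machinery, Adcy5, the main cardiac adenylyl cyclase with Adcy6, fell, at −2.57 ± 0.33 (−1.87 within slide 1) and the alpha-1B receptor gene Adra1b at −1.92 ± 0.22 (−2.25), while Rgs2 and Rgs4, which shorten G-protein signals, rose by 1.73 ± 0.20 (1.94) and 1.70 ± 0.21 (1.87). The receptor gene Adrb1 did not pass, at −0.22 ± 0.18 (adjusted p = 0.41). Pde4d, a cAMP phosphodiesterase, was at −0.15 ± 0.25 (adjusted p = 0.698), and its 5 probes differed in direction. Of 34 genes tested 4 rose, 3 fell and 27 did not pass, with the same numbers when adjusted over the list alone. Limma's fry, another list test, called the list (adjusted p = 0.043), but camera did not. The median was −0.23 with a camera adjusted p of 0.134 and adjusted p = 0.372 with an estimated correlation. Within slide 1 it was −0.13 (adjusted p = 0.203), and under normexp 0.11 with a camera call of lower (adjusted p = 0.0472).

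Most genes of fatty acid oxidation fell, the broadest change among the lists. Pdk4, a kinase that restrains glucose oxidation, fell, at −4.32 ± 0.28, Cpt1b, which admits fatty acids to cardiac mitochondria, at −2.66 ± 0.17 (−2.56 within slide 1), the fatty acid transporter Cd36 at −2.48 ± 0.17 (−2.54) and Cpt1a, detected on 2 isoproterenol arrays, at −2.21 ± 0.23 (−2.27). Of 35 genes tested 0 rose, 25 fell and 10 did not pass, and 27 fell when adjusted over the list alone. The median was −1.19, and camera gave adjusted p = 2.72e-17, but adjusted p = 0.236 with an estimated correlation. Within slide 1 the median was −1.51 (adjusted p = 1.17e-25).

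**Figure D3:**
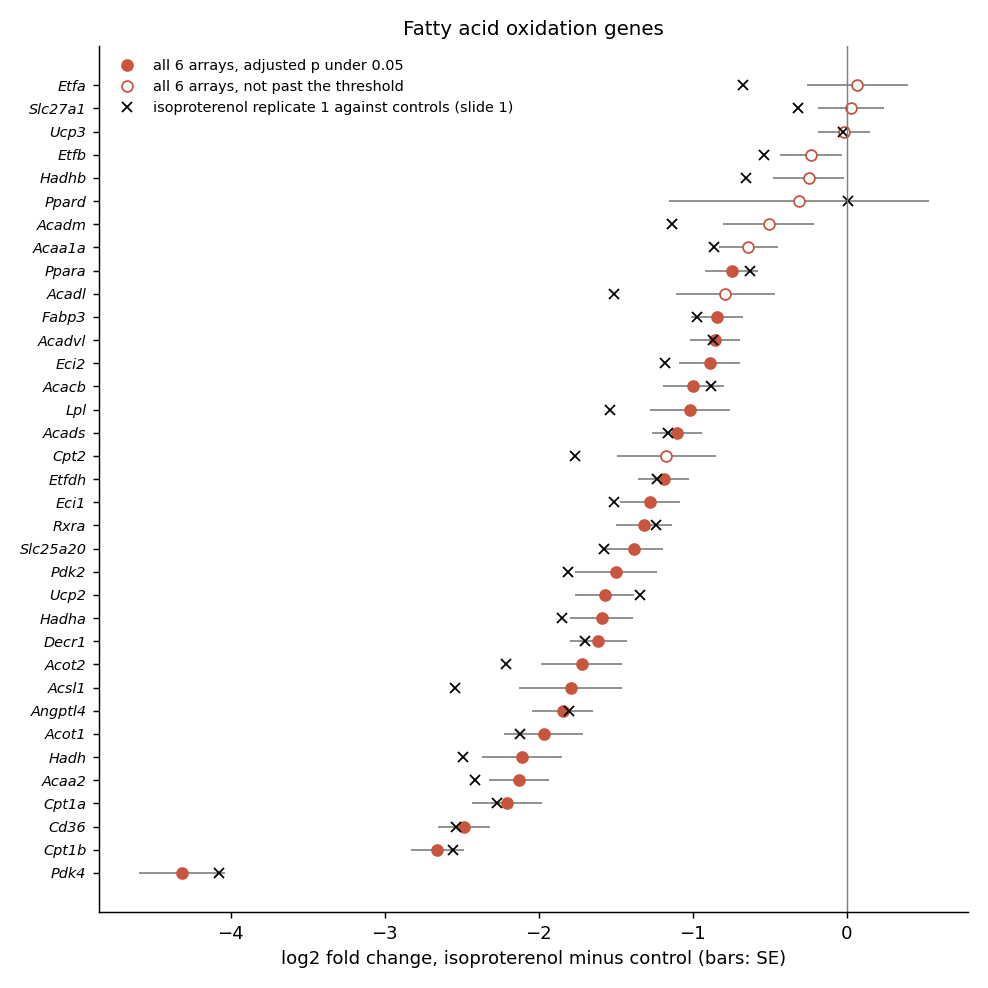
Log2 fold change, isoproterenol minus control, of the 35 fatty acid oxidation genes tested (circles with SE, n = 3 per group; filled circles passed the adjusted p threshold of 0.05), with isoproterenol replicate 1 minus the control mean as crosses. The 25 filled circles all lie below 0.

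Oxidative phosphorylation genes showed 0 rises, 1 fall and 42 genes that did not pass among 43 tested, with the same numbers when adjusted over the list alone. The gene that fell was Cox8b, a cytochrome oxidase subunit, at −1.07 ± 0.18 (−1.28 within slide 1). The median was 0.12 and camera's adjusted p 0.975 (adjusted p = 0.994 with an estimated correlation), but the median was −0.20 within slide 1 (adjusted p = 2.38e-04) and −0.23 under quantile normalization (adjusted p = 0.002), both lower, while it was −0.02 under normexp and −0.12 with scaling over probes detected on all arrays. Glycolytic genes moved apart: Hk2, a hexokinase, rose by 2.42 ± 0.32 (1.88 within slide 1) and Pfkp, a phosphofructokinase, by 2.23 ± 0.39 (1.40, adjusted p = 0.055 there), while Aldoc, an aldolase, fell, at −2.08 ± 0.29 (−2.14, adjusted p = 0.0507 there) and Ldhb, the lactate dehydrogenase subunit of the heart, at −2.06 ± 0.17 (−1.95). Of 30 genes of glycolysis and glucose uptake 11 rose, 7 fell and 12 did not pass, and 13 rose and 8 fell when adjusted over the list alone. The median was 0.42 with a camera adjusted p of 0.698 and adjusted p = 0.956 with an estimated correlation, and within slide 1 the median was 0.16 (adjusted p = 0.941).

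Targets of cAMP signalling and immediate early genes were higher after 24 h. Sik1, a kinase induced through CREB and detected on 2 control arrays, rose by 3.26 ± 0.21 (2.98 within slide 1), the stress transcription factor Atf3 by 3.29 ± 0.53 (2.58, adjusted p = 0.0946 there), Ier3 by 2.25 ± 0.35 (1.48) and Id1, an inhibitor of helix-loop-helix factors, by 2.17 ± 0.25 (2.12). Nr4a1, an orphan nuclear receptor, was at −0.59 ± 0.30 (adjusted p = 0.213, 0.07 within slide 1), and Crem, the cAMP-responsive modulator, at 0.33 ± 0.17 (0.202), its 5 probes differing in direction. The lowest value of Sik1 under the alternatives was 1.67. Of 33 genes tested 14 rose, 1 fell and 18 did not pass, and 17 rose and 2 fell when adjusted over the list alone. As a list they were higher (median 0.81, adjusted p = 0.00222, adjusted p = 0.372 with an estimated correlation), with a median of 0.68 within slide 1 (adjusted p = 2.38e-04). Without isoproterenol replicate 1 the adjusted p was 0.0791.

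Inflammatory cytokines and NF-kB targets were higher. Besides Cxcl2, the cytokine Il11 rose by 3.03 ± 0.26 (2.74 within slide 1), the prostaglandin synthase Ptgs2 by 2.91 ± 0.33 (2.91) and Il1rl1, the receptor of interleukin 33, by 2.85 ± 0.18 (2.94). Of 23 genes tested 7 rose, 0 fell and 16 did not pass, and 9 rose when adjusted over the list alone. Camera called them higher (median 0.59, adjusted p = 9.36e-04, adjusted p = 0.211 with an estimated correlation), and within slide 1 the median was 0.66 (adjusted p = 0.00264). Interferon response genes were lower: Usp18 fell, at −1.77 ± 0.45 (−2.75 within slide 1, adjusted p = 0.0892 under quantile normalization), Irf7 at −1.33 ± 0.29 (−1.88), Irf1 at −1.53 ± 0.33 (−0.83, adjusted p = 0.0977 there) and Stat2 at −1.05 ± 0.17 (−1.02). Usp18, Irf1 and Stat2 were detected on 1 isoproterenol array, and under normexp Irf1 was at 0.02 and Stat2 at 0.05. Of 20 genes tested 0 rose, 5 fell and 15 did not pass, with the same numbers when adjusted over the list alone. The list was lower (median −0.33, adjusted p = 0.0118, adjusted p = 0.318 with an estimated correlation). Within slide 1 the median was −0.29 (adjusted p = 2.98e-04), under normexp 0.03 with a camera call of lower (adjusted p = 0.0472), and without isoproterenol replicate 1 the adjusted p was 0.0873.

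Cell cycle genes were higher. The cyclin gene Ccnd1 rose by 2.31 ± 0.33 (1.77 within slide 1, adjusted p = 0.058 there), Cdc6, which loads the replicative helicase, by 1.49 ± 0.19 (1.33), Mcm6, a helicase subunit, by 1.46 ± 0.30 (0.83, adjusted p = 0.0813 there) and Ccna2 by 1.42 ± 0.29 (0.94, adjusted p = 0.139 there). Of 37 genes tested 10 rose, 0 fell and 27 did not pass, and 12 rose when adjusted over the list alone. Camera called the list higher (median 0.61, adjusted p = 5.71e-05, adjusted p = 0.372 with an estimated correlation), with a median of 0.51 within slide 1 (adjusted p = 2.38e-04). Among p53 and apoptosis genes, Gadd45g rose by 2.76 ± 0.60 (1.88, adjusted p = 0.211 there), Bnip3 by 1.38 ± 0.35 (0.60, 0.122) and Phlda3 by 1.24 ± 0.23 (0.82, 0.0547), while the pro-apoptotic gene Bcl2l11, detected on 1 isoproterenol array, fell, at −1.64 ± 0.41 (−1.35, 0.238) and was at 0.13 under normexp. Of 27 tested 5 rose, 1 fell and 21 did not pass, and 6 rose and 1 fell when adjusted over the list alone. The list was called by fry (adjusted p = 0.0316) but not by camera. The median was 0.39 with a camera adjusted p of 0.105 (adjusted p = 0.648 with an estimated correlation), and within slide 1 it was 0.22 (adjusted p = 0.359).

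Genes of the endoplasmic reticulum stress response were higher. Ppp1r15a, which ends the block of translation in stress, rose by 1.80 ± 0.39 (1.03 within slide 1, adjusted p = 0.152 there), Creld2 by 1.48 ± 0.25 (1.38, 0.0795), the stress sensor Atf6 by 1.25 ± 0.21 (1.15, 0.0713) and Sdf2l1 by 1.24 ± 0.17 (1.20). Of 25 tested 6 rose, 1 fell and 18 did not pass, and 14 rose and 1 fell when adjusted over the list alone. The list as a whole was higher (median 0.77, adjusted p = 0.00204, adjusted p = 0.318 with an estimated correlation), with 0.53 within slide 1 (adjusted p = 0.0049). Of 17 heat shock genes 3 rose, 0 fell and 14 did not pass: Hsph1 by 1.66 ± 0.22 (1.27 within slide 1), Hspa4 by 1.20 ± 0.30 (0.58, adjusted p = 0.162 there) and Hsp90aa1 by 1.19 ± 0.28 (0.60, 0.102). Adjusted over the list alone, 8 rose. Camera called the list higher (median 0.42, adjusted p = 0.00207, adjusted p = 0.648 with an estimated correlation), but within slide 1 the median was 0.17 and the call ended (adjusted p = 0.113), as under normexp (adjusted p = 0.238). Of 25 oxidative stress genes 7 rose, 2 fell and 16 did not pass, and 10 rose and 4 fell when adjusted over the list alone. The cystine transporter Slc7a11 rose by 2.61 ± 0.26 (2.10 within slide 1), Txnrd1 by 1.48 ± 0.26 (0.99, adjusted p = 0.0589 there), Nqo1 by 1.36 ± 0.21 (1.05) and Txn1 by 1.04 ± 0.26 (0.54, 0.148). That list's median was 0.48 with a camera adjusted p of 0.154 (adjusted p = 0.712 with an estimated correlation), and −0.02 within slide 1 (adjusted p = 0.974).

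Ribosomal protein genes were higher as a list but hardly as single genes. Of 36 tested 1 rose, 0 fell and 35 did not pass, and adjusted over the list alone 0 rose. The gene that rose was Rplp1, at 0.88 ± 0.23 (adjusted p = 0.0477, 0.46 within slide 1, adjusted p = 0.142). Camera called this list higher (median 0.65, adjusted p = 4.97e-05, adjusted p = 0.648 with an estimated correlation), with 0.23 within slide 1 (adjusted p = 0.0151), while under quantile normalization the median was 0.07 and the call ended (adjusted p = 0.252), as it did under normexp (adjusted p = 0.052). The brightest 3995 genes had median changes of 0.53 and 0.47 on the slide 2 arrays and 0.11 in isoproterenol replicate 1. Random lists as bright as the ribosomal protein genes had a median of 0.74 on slide 2 and 0.10 in isoproterenol replicate 1. Of 14 circadian clock genes 1 rose, 0 fell and 13 did not pass, and 1 rose and 1 fell when adjusted over the list alone. The gene that rose was Per2, at 1.78 ± 0.33 (1.08 within slide 1, adjusted p = 0.0585), and the clock list had a median of −0.15 with a camera adjusted p of 0.408 (adjusted p = 0.648 with an estimated correlation), 0.04 within slide 1 (adjusted p = 0.511) and 0.19 under normexp.

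Matrix and remodelling genes were higher on balance. The growth factor Tgfb2 rose by 3.20 ± 0.81 (2.51 within slide 1, adjusted p = 0.269 there), and the matricellular genes Ccn2 and Ccn1 by 2.29 ± 0.49 (1.74, 0.192) and 2.08 ± 0.29 (1.78, 0.0613). Under quantile normalization Tgfb2 and Ccn2 had adjusted p = 0.0849 and 0.0669. The value of Tgfb2 ranged from 2.45 to 4.16 over the alternatives. Of 31 tested 9 rose, 3 fell and 19 did not pass, and 14 rose and 4 fell when adjusted over the list alone. By camera the list was higher (median 0.52, adjusted p = 0.0133, adjusted p = 0.648 with an estimated correlation), but within slide 1 the median was 0.27 and the call ended (adjusted p = 0.264), as under normexp (adjusted p = 0.452). Fibroblast markers included Lum at −1.60 ± 0.22 (−1.54 within slide 1), Postn at −1.32 ± 0.22 (−0.93) and Col3a1 at −1.10 ± 0.20 (−0.92, adjusted p = 0.0712 there), which fell, and Pdpn, which rose by 1.19 ± 0.26 (0.65, 0.0795). Of 17 fibroblast markers, which share 3 collagen genes with the matrix list, 3 rose, 4 fell and 10 did not pass, and 4 rose and 4 fell when adjusted over the list alone. Their median was −0.20 with a camera adjusted p of 0.319 (adjusted p = 0.712 with an estimated correlation), and −0.19 within slide 1, where the list was called lower (adjusted p = 0.0476), as it was under normexp (adjusted p = 0.00412).

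Markers of the remaining cell types did not pass as lists by camera over all arrays. Limma's fry called the epicardial and mesothelial list (adjusted p = 0.00919) and the Schwann and neuronal list (0.0255). Of 12 smooth muscle and pericyte markers 2 rose, 1 fell and 9 did not pass, and 4 rose and 1 fell when adjusted over the list alone. Tagln rose by 1.77 ± 0.35 (1.03 within slide 1, adjusted p = 0.0756 there), Myocd by 1.41 ± 0.23 (0.98) and Smtn fell, at −0.81 ± 0.18 (−0.78, 0.0841). The median was −0.22 and the mean 0.28, with a camera adjusted p of 0.973 (adjusted p = 0.974 with an estimated correlation) and a median of 0.21 within slide 1 (adjusted p = 0.834). Of 16 endothelial markers 2 rose, 2 fell and 12 did not pass, and 3 rose and 5 fell when adjusted over the list alone. The receptor gene Flt1 rose by 2.10 ± 0.25 (1.79), though its 2 probes differed in direction, and Plvap by 0.86 ± 0.17 (0.75, 0.076), while Kdr fell, at −1.22 ± 0.17 (−1.27) and Cldn5 at −1.06 ± 0.20 (−1.19, 0.0567), the latter pair detected on 1 isoproterenol array and under normexp at −0.0590 (adjusted p = 0.870) and −0.00863 (0.983). The endothelial median was −0.28 with a camera adjusted p of 0.28 (adjusted p = 0.648 with an estimated correlation) and a median of −0.00389 within slide 1 (adjusted p = 0.571). Of 20 macrophage and leukocyte markers 3 rose, 1 fell and 16 did not pass, with the same numbers when adjusted over the list alone. Fcgr2b rose by 1.31 ± 0.17 (1.17), Cd14 by 1.24 ± 0.25 (0.97, 0.124) and S100a8 by 1.02 ± 0.18 (1.04, 0.0508), while Cd3e, detected on 1 isoproterenol array, fell, at −1.62 ± 0.32 (−1.13, 0.132) but was at 0.12 under normexp. The leukocyte median was −0.05 with a camera adjusted p of 0.768 (adjusted p = 0.956 with an estimated correlation), and 0.12 within slide 1 (adjusted p = 0.571).

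Of 7 epicardial and mesothelial markers 2 rose, 1 fell and 4 did not pass, and 3 rose and 1 fell when adjusted over the list alone. The keratin genes Krt18 and Krt8 rose by 2.60 ± 0.25 (2.22 within slide 1) and 1.68 ± 0.21 (1.36), and Aldh1a2, which makes retinoic acid, fell, at −1.59 ± 0.25 (−1.38, adjusted p = 0.073 there, detected on 2 isoproterenol arrays). The median was 0.23 with a camera adjusted p of 0.408 (adjusted p = 0.648 with an estimated correlation), and 0.24 within slide 1 (adjusted p = 0.359). Of 10 Schwann and neuronal markers 0 rose, 2 fell and 8 did not pass, with the same numbers when adjusted over the list alone: S100b, detected on 1 isoproterenol array, fell, at −1.31 ± 0.16 (−1.30, and −0.00657 under normexp, adjusted p = 0.988) and Prph at −0.97 ± 0.17 (−1.07). Their median was 0.09 and mean −0.09, with a camera adjusted p of 0.534 (adjusted p = 0.648 with an estimated correlation) and a median of 0.16 within slide 1 (adjusted p = 0.375). Of 8 erythroid markers 1 rose, 2 fell and 5 did not pass, and 2 rose and 3 fell when adjusted over the list alone. The globin genes Hbb-b1 and Hbb fell, at −1.01 ± 0.17 (−0.99 within slide 1) and −0.84 ± 0.19 (−0.78, adjusted p = 0.102 there), Hbb being at 0.07 under normexp, and Ahsp rose by 0.98 ± 0.25 (0.70, 0.217). Hbb and Ahsp were detected on 1 isoproterenol array. The erythroid median was −0.37 with a camera adjusted p of 0.28 (adjusted p = 0.648 with an estimated correlation), but within slide 1 it was −0.72 and the list was called lower (adjusted p = 0.0274). Under normexp the medians of the smooth muscle, endothelial, leukocyte and erythroid lists were 0.15, 0.27, 0.11 and 0.15. Under quantile normalization that of the Schwann and neuronal list was −0.24, and with scaling over probes detected on all arrays that of the epicardial list was −0.0111.

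**Figure D4:**
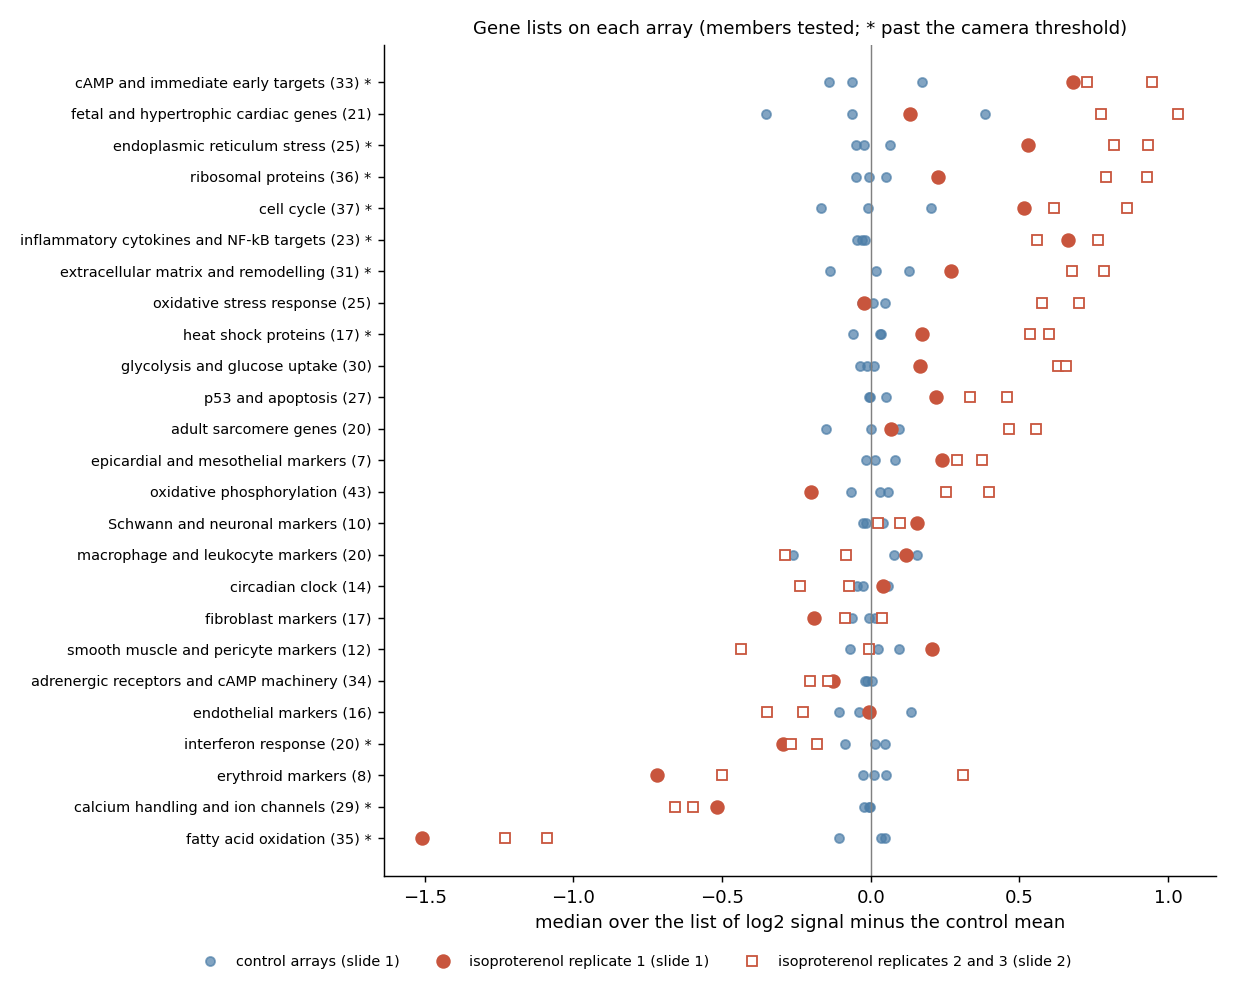
Median over the members of each gene list of the log2 signal minus the control mean, per array (blue: control arrays; filled red: isoproterenol replicate 1 on slide 1; open squares: isoproterenol replicates 2 and 3 on slide 2). The number of genes tested stands in brackets and an asterisk marks the 10 lists past the camera threshold. Fatty acid oxidation lies lowest on each isoproterenol array.

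Of 25 lists 10 passed the camera threshold, 7 higher and 3 lower, and 0 did with an estimated correlation, while fry called 14. On slide 2, where probes were less often detected and negative-control signals were higher, the medians of the higher lists lay above those of isoproterenol replicate 1, except that the inflammatory list's medians lay on both sides of it.

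Of 8952 lncRNA probes 387 changed, 224 higher and 163 lower, and 347 changed at least 2-fold, 201 higher and 146 lower. Among the largest rises were those of XR_341985, by 4.80 ± 0.36 (adjusted p = 0.00376, 3.98 within slide 1), and XR_594604, at least 6.83-fold higher, detected on 0 control arrays and 3 isoproterenol arrays (adjusted p = 0.0213, and 0.0637 under quantile normalization). Among the largest falls were those of XR_600214, at −4.70 ± 0.33 (−5.03 within slide 1, detected on 1 isoproterenol array), and XR_344829, at −4.22 ± 0.34 (−4.39). The only named RNA among the leading lncRNA probes was LOC102555456, which fell, at −3.21 ± 0.59 (adjusted p = 0.0376, and 0.0667 under quantile normalization; −4.45 within slide 1) and was detected on 1 isoproterenol array. XR_594604, XR_600214 and LOC102555456 did not pass under normexp, at 1.38, −2.02 and −1.28. With slide as a block 91 probes changed, 35 higher and 56 lower, of which 72 were among the 387, on slide 1 alone 12, and with quantile normalization and the slide block 0. Quantile normalization gave 200, normexp 191 and scaling over probes detected on all arrays 135 higher and 246 lower. Leaving out control replicate 1, 2 or 3 gave 115, 24 or 21 probes, and leaving out isoproterenol replicate 1, 2 or 3 gave 3885, 49 or 37.

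Of 13 probes of lncRNAs with an established name, 0 passed limma's moderated test over all lncRNA probes or adjusted over the list alone, while 4 had an unadjusted p under 0.05. These were Xist, which silences the X chromosome, at 0.87 ± 0.23 (adjusted p = 0.0803), Dancr at 1.34 ± 0.45 (0.128), Ftx at 0.78 ± 0.27 (0.134) and Hotairm1 at 1.70 ± 0.66 (0.16). Meg3 was at −0.25 ± 0.22, H19 at −0.33 ± 0.26, Miat at −0.42 ± 0.27 and Tug1 at −0.24 ± 0.22, and Gas5, a host of small nucleolar RNAs, was at 0.28 ± 0.26 but at −0.16 under quantile normalization and −0.27 within slide 1. Without isoproterenol replicate 1 the number past the threshold was 8.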

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

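The tests on the slides, on the scaling, on bright probes of slide 2 and on control replicate 1 were chosen only after the results they bear on had been seen. Among probes that the deposited tables do not list, 136 were detected on at least 3 arrays, and 17 of these were higher and 3 lower with isoproterenol; the signal lay outside the comparison reported and the probes are not named here.

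The 2769 changed mRNA genes could come from the difference between the slides as the whole cause, since 2 of the isoproterenol arrays stand alone on slide 2. With control replicate 1, 2 or 3 held out, 9141, 7626 or 7056 genes were called from the remaining 2 controls against the slide 2 arrays. These are larger sets than the 2769, and their groups lie wholly on different slides. Their genes lay on the same side in isoproterenol replicate 1, against the held-out control, in 73.0% to 76.1% of cases over the 3 controls. The bound of 75% set for excluding the slide was missed in 1 of them. The share was 83.0% to 86.1% for genes that rose and 59.3% to 64.2% for genes that fell, against 54.5% to 56.8% for genes not called, but the bound had not been set by direction, and for the full set slide and treatment cannot be told apart. A test on part of the genes was added after that result: 931 were called again with slide as a block. That contrast is taken within slide 1, where the slide cannot produce it, though it rests on 1 isoproterenol array. The 2769 genes had been picked partly through that array, which lay on the called side in all of them, so the test is not independent. Under quantile normalization 75.8% were called again in the same direction, which narrowly passes a bound of 75%. Of the 2769 genes, 2057 were called again under median scaling and 2020 under normexp, both short of 75%. With scaling over probes detected on all arrays 2221 were called again. These counts argue against scaling as the whole cause of the calls, but not against a part in them.

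The 6 arrays allow 10 splits, too few for a share under 0.05: only the real split, 1 of 10, gave 2769 genes, 2018 at least 2-fold, 387 lncRNA probes and 347 at least 2-fold, against 0 in the highest other; 10 lists passed in 1 split, against 9, and for named lncRNAs all 10 splits gave 0.

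The higher ribosomal protein genes may reflect the difference of the slide 2 arrays in bright probes: there the list's median stood at percentile 87.8 of random lists of equally bright genes, within their middle range. In isoproterenol replicate 1, on the slide of the controls, it stood at percentile 99.9, which is consistent with isoproterenol raising these transcripts but comes from 1 array. Neither explanation was excluded. On slide 2 and in isoproterenol replicate 1 the heat shock list stood at percentiles 77.8 and 73.7, and the fatty acid oxidation list at 0 and 0. The oxidative phosphorylation list stood at percentiles 8.52 and 0. Its medians there were 0.31 and −0.20, against 0.56 and 0.14 for random lists of equally bright genes.

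Fetal and hypertrophic genes were high in control replicate 1, and isoproterenol-treated material in that array is a candidate explanation, which would move genes in both directions by the same linear fraction of the way to the isoproterenol mean. The first test, on 152 genes called at least 4-fold lower without that array, gave a median fraction of 0.355 (0.268 for 274 genes called or not), close to the 0.317 of the 10 list members, as treated material would give. After that result a second test was chosen, on 225 other genes called at least 4-fold higher without that array, and it gave 0.0803, and 0.0797 for 255 genes called or not, with upper quartiles of 0.175 and 0.177 under the lower quartile of 0.251 of the list members, which needed no call. The list members had been taken at a lower cut, at least 2-fold higher, where the same deviation makes a larger fraction, so the comparison is uneven. In a lowered gene the linear distance to the isoproterenol mean cannot exceed the control signal. The same log2 deviation therefore makes a larger fraction there than in a strongly raised gene. The first test thus cannot tell treated material from deviations of like log2 size in both directions. Within these limits the raised genes argue against an even share of treated material as the whole cause of the fetal genes' values, while the lowered genes cannot decide. Since the second test was picked after the first, the matter stays partly open. No biological explanation was tested.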

How the results depend on the processing

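The fit to slide 1 alone and quantile normalization with slide as a block were tried only after the data had been seen; the other alternatives were planned. Counts of changed mRNA genes, those changed at least 2-fold, lncRNA probes and those changed at least 2-fold were 2769, 2018, 387 and 347. With slide as a block they were 1105, 946, 91 and 91, on slide 1 alone 480, 480, 12 and 12, and with quantile normalization and the slide block 752, 701, 0 and 0, where the contrast rests on fewer arrays. Array weights gave 13547, 5413, 5747 and 2634, with weights from 0.1003 for isoproterenol replicate 1 to 4.76 for isoproterenol replicate 3. That fit thus comes near to leaving out the only isoproterenol array of slide 1, which gave 10006, 5139, 3885 and 2325. Whether this accounts for the rise in counts was not tested. An unadjusted p under 0.05 passed 6907 genes, 2436 probes and 1125 probes at least 2-fold. Normexp gave 1276 genes at least 2-fold and 191 and 149 lncRNA probes, quantile normalization 200 and 190 probes, and detection on all 6 arrays 873 of 3664 probes, for reasons that were not tested. Other filters, probe rules and scalings stayed within 1.5 times the count. Detection on all 6 arrays gave 4082 of 12306 mRNA genes, against 2769 of 19975. Dropping the detection filter left the same 19975 mRNA genes to test, since all 20691 matched mRNA probes had passed it. Of the matched lncRNA probes 99.3% had passed it, so that setting could hardly change the counts and does not test the filter.

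No pairing by replicate number was seen: same-numbered arrays had correlations of 0.00438, 0.0476 and −0.0225 in their deviations, and none correlated best with its own number. Deviations of the isoproterenol arrays hold the slide difference, which could hide a shared culture, so pairing is not excluded. With the replicate block the counts were 749, 749, 43 and 43. Leaving out single arrays gave 140 to 10006 genes, 140 to 5139 at least 2-fold, 21 to 3885 probes and 21 to 2325 at least 2-fold; the lowest came without control replicate 3 and the highest without isoproterenol replicate 1, when each group lies on its own slide. Probes of named lncRNAs past the threshold numbered 1 with detection on all 6 arrays, 9 with array weights, 4 at an unadjusted p, and 0 to 8 with single arrays left out.

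Lists past the threshold numbered 8 to 11 under the alternatives, 14 with fry, and 0 with an estimated correlation. The oxidative phosphorylation list, at 0.12 and not called, turned to −0.0247 under normexp, −0.23 under quantile normalization and with the deposited values, −0.20 with the slide block and on slide 1 alone, and −0.34 with both, each called lower, and the cause was not tested. Of 113 named genes called, 69 were called again with the slide block, 43 on slide 1 alone, 96 under quantile normalization and 95 under normexp. Under quantile normalization Ahsp, Gadd45g, Bcl2l11, Bnip3, Txn1, Rplp1, Hspa4 and Hsp90aa1 were among those not called again. Under normexp 5 turned: Cd3e to 0.12, Hbb to 0.0739, Bcl2l11 to 0.13, Irf1 to 0.0171 and Stat2 to 0.0505, each detected on 1 isoproterenol array; Nppc, Kcnip2, Usp18, Kdr, Cldn5, S100b, Aldh1a2, Prph and Ahsp were not called again, and the cause was not tested. Since the offset of 50 under normexp pulls changes of dim genes toward 0, losses there are no independent evidence against these falls. The lower signal over background on slide 2 limits what can be said of dim genes, and 285 of the 1048 genes that fell were undetected on both of its arrays.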

Other observations

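The lists in this part, the lncRNA pairs apart, were chosen after the data had been seen, several with their leading genes already known. Their counts and camera p-values are therefore descriptions and not tests. Genes of branched-chain amino acid catabolism were lower: of 21 tested 9 fell, among them Hibch at −2.03, Aldh6a1 at −1.83 and Bcat2 at −1.56, while the cytosolic transaminase Bcat1 rose by 2.00 (median −0.73, camera adjusted p = 2.25e-04; adjusted p = 0.277 with an estimated correlation; −1.03 within slide 1). Cholesterol synthesis genes were higher, with 6 of 17 risen, including Sqle at 1.95 (median 0.41, adjusted p = 0.0141; adjusted p = 0.277 with an estimated correlation; 0.49 within slide 1; 5 rose under quantile normalization). Of 19 genes of the tricarboxylic acid cycle 2 fell, Ogdh among them (median −0.22, adjusted p = 0.206; adjusted p = 0.653 with an estimated correlation; −0.41 within slide 1), and under quantile normalization the list was called lower (adjusted p = 0.00515).

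Of 23 ribosome biogenesis genes 13 rose, led by Bop1 at 1.91 and Rrp9 at 1.80 (median 0.95, adjusted p = 5.27e-06; adjusted p = 0.277 with an estimated correlation; 0.69 within slide 1), 4 of 13 aminoacyl-tRNA synthetase genes rose (median 0.88, adjusted p = 0.00917; adjusted p = 0.353 with an estimated correlation; 0.77 within slide 1), and 3 of 12 amino acid transporters rose (median 0.85, adjusted p = 3.93e-04; adjusted p = 0.277 with an estimated correlation; 0.51 within slide 1). Proteasome genes showed 5 rises among 26 (median 0.72, adjusted p = 2.47e-05; adjusted p = 0.277 with an estimated correlation; 0.40 within slide 1). Under quantile normalization 0 of the synthetase and 0 of the proteasome genes passed, with medians of 0.64 and 0.39, against 10 of ribosome biogenesis and 3 transporters. Of 18 actin and serum response factor targets 8 rose, including Actb at 2.07 and Zyx at 1.67 (median 1.13, adjusted p = 2.47e-05; adjusted p = 0.277 with an estimated correlation; 0.62 within slide 1; 5 rose under quantile normalization), and of 13 genes of MAP kinase feedback 4 rose (median 0.73, adjusted p = 0.0115; adjusted p = 0.277 with an estimated correlation; 0.47 within slide 1). Of 8 ligands of the EGF family 3 rose, Ereg at 3.70, Hbegf at 3.52 and Areg at 1.43 (adjusted p = 0.0704; adjusted p = 0.277 with an estimated correlation; median 0.75 and 0.39 within slide 1).

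The hypothesis that a lncRNA changes with its nearest protein-coding neighbour was tested on 347 pairs, limited to lncRNA genes that could be named. The neighbour was the nearest among the mRNA genes tested, so an untested gene could lie nearer. For these pairs the hypothesis was not borne out. Across them, which are not independent replicates, Spearman's rho was 0.0481 (permutation p = 0.371) and Pearson's r 0.0532 (permutation p = 0.321). Of the 22 changed lncRNAs among them 6 had a changed neighbour, 5 in the same direction.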
